A study of Homo sapiens with 6 samples.

How the data were processed

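Total RNA of HepG2 cells was measured in 6 libraries, 3 from untreated and 3 from GDF11-treated cultures, which the labels call biological replicates. Per the labels' protocols, directional libraries were made from 250 ng of RNA and sequenced as single reads of 75 bases. The authors' processing is described in more than 1 way: per the submitters' processing notes, Trimmomatic, Salmon 1.2.1, DESeq2 and the GRCh38 build were used, while the labels' protocol text names STAR 2.6 and hg19. Which of these gave the table is not given in the sources used here. The authors deposited 1 table of log2 values for 60240 Ensembl genes, named as variance-stabilised. Every gene without reads has the value 5.52 in it, and 26643 genes have that value in all 6 libraries. How the RNA was selected is not given in the sources used here.

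The scale was checked on the low values. After inversion of the variance-stabilising curve, 71.0% to 74.2% of the low values of a library (up to 20 reads) fell on whole reads within 0.01. The rest did not, so whole reads were not recovered and no count test was run. The step of 1 read gave an estimated depth of 47900000 to 53400000 reads per library. The labels' protocols name a MiSeq, an instrument whose runs are known to give fewer reads than this for even 1 such library, and how the 2 fit together is not given in the sources used here. Small changes are compressed at low values: at a value of 8 the scale keeps 0.696 of a true log2 change, at 10 it keeps 0.914 and at 12 it keeps 0.978. Back-transformed reads are normalised to a common depth, and folds given on them are ratios of group means. On a log2 scale of these reads plus 1, differences near the lowest value were larger, for example 9.11 for R3HDML and -3.96 for CYP7A1. Within a group, replicate pairs had Pearson correlations of 0.991 to 0.997 across genes and differed by more than sampling noise (chi-square per degree of freedom 26.4 to 220.3), so that no 2 looked like copies of 1 library. Mitochondrially encoded genes held 4.43% to 6.94% of the back-transformed reads.

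Genes entered the test with a mean of at least 0.5 above the lowest value, which left 18723. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend, two-sided), all 6 libraries and no covariate, with Benjamini-Hochberg adjustment at 0.05 over all tested genes. A gene was called when its adjusted p was under 0.05, and standard errors are limma's moderated ones. Gene lists were tested with camera (preset correlation, adjusted over the 45 lists), and again with an estimated correlation, on ranks, and with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. The share of variance between the groups used the 1000 most variable genes and the exact 10 splits. On simulated data for this comparison, with 200 of 18723 genes changed, 2.0% of changes of 0.5, 62.0% of changes of 1, 88.0% of changes of 2 and 100% of changes of 4 were called, and 5.26% of calls were false. In those data 1 shifted list was called and 0 of 40 unshifted lists. The simulated genes varied independently and the lists were random genes. The simulation therefore cannot show how camera at its preset correlation treats lists whose genes vary together. In the real data 4202 genes were called, far more than the 200 changed in the simulation. The share of changes recovered and the share of false calls can therefore differ in the real data.

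The lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. That rule takes the 10 largest increases and 10 largest decreases among called genes with a symbol whose groups do not overlap, 14 genes taken whatever their result (12 of them given here: SMAD7, SKIL, PMEPA1, ID1, PLIN2, SCD, FASN, SREBF1, DGAT2, CPT1A, APOB and ALB), and up to 4 members of each described list with the lowest unadjusted p; GDF11 itself and list members named as listed at the lowest value, or below the filter, were added after their values were seen. Gene names came from a table that matched 58349 of the 60240 IDs (96.9%); CD24, PECAM1, BOP1 and DDX58 were not matched. Positions are from the GRCh38.p14 RefSeq table, looked up by symbol. Transcript GC content and length, from a GRCh37 annotation, were had for 99.1% of the tested genes and served only for the trend of library values on these properties. The alternatives covered filters, normalization, the variance prior, library weights, the RNA integrity number, a replicate block, thresholds and leaving out each library; removal of the GC and length trend, with or without control replicate 3, and a log2 scale of back-transformed reads plus 1 were added later.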

Results

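HepG2 is a human hepatocellular carcinoma line. Cultures received 100 ng/ml recombinant GDF11 (growth differentiation factor 11, a secreted protein of the TGF-beta family) for 24 h or no GDF11, and total RNA from 3 biological replicates of each kind was sequenced as 75-base single reads. The comparison of the 3 GDF11 with the 3 control libraries asks which transcripts differ after 24 h, with lipid handling and signalling through the type I receptor ALK5 as the subjects of the series title. Values stand on a variance-stabilised log2 scale, on which a gene without reads has the value 5.52. The estimated depth was 47900000 to 53400000 reads per library. RNA integrity numbers were 9.8, 9.9 and 9.6 in control replicates 1, 2 and 3, and 9.6, 9.5 and 9.4 in GDF11 replicates 1, 2 and 3.

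GDF11-treated cells held more RNA of TGF-beta target, matrix, cytoskeletal and immediate early genes, and less RNA of DNA replication, hepatocyte-specific and several lipid metabolism genes by camera. Control replicate 3, though untreated, lay part of the way to the GDF11 libraries over the lower lipid lists. Its median position was 0.63 (lipogenesis), 0.47 (oxidation), 0.70 (cholesterol) and 0.71 (apolipoproteins), against -0.0027 for G1/S. On that scale 0 is the mean of the other controls and 1 the GDF11 mean, over members that differ by at least 0.5 between them. Some lists share genes and are not independent. COL1A1 and MMP9 are in the TGF-beta target and matrix lists, and JUNB is in the TGF-beta target and immediate early lists. None of the 45 gene lists is called when the correlation between genes is estimated (lowest adjusted p = 0.0552 with an estimated correlation). JUNB, a transcription factor gene of the AP-1 family and a TGF-beta target, rose from 9.59 ± 0.041 to 13.63 ± 0.16 (mean ± SD, n = 3 each), 18.6 times the control on back-transformed reads. FGA, which encodes the fibrinogen alpha chain made by hepatocytes, fell from 16.23 ± 0.29 to 14.02 ± 0.051, and the control level was 4.68 times that with GDF11. Of 18723 genes tested with limma, 2185 were higher and 2017 lower with GDF11 at a Benjamini-Hochberg adjusted p under 0.05. By at least 1 on the log2 scale, 803 genes rose and 554 fell, and by at least 2, 171 rose and 40 fell. The 3 values of each group did not overlap for 40.5% of the tested genes, where chance gives 10%.

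Between the groups lay 83.7% of the variance of the 1000 most variable genes. This is the largest share among the 10 splits of the libraries into 3 and 3, the next being 18.999%. Each other split mixes control and GDF11 libraries, so a large share in the real split by itself leaves little for the others. The exact p of 0.1 is the smallest that 3 against 3 can give. Control replicate 3 stood apart from the other controls, at -20.0 on the first principal component against -46.5 and -52.2, with the GDF11 libraries at 35.2 to 45.4. Without control replicate 3, 3647 genes were higher and 3993 lower. The counts of higher and lower genes were 1416 and 1094 without control replicate 1, 1614 and 1189 without control replicate 2, 1397 and 1001 without GDF11 replicate 1, 1517 and 1144 without GDF11 replicate 2, and 1462 and 955 without GDF11 replicate 3. With the RNA integrity number as a covariate they were 1149 and 721.

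The largest increases among genes whose groups did not overlap were in ALPG, a germ cell type alkaline phosphatase, by 6.42 ± 0.17 on the log2 scale (difference ± SE, 3 against 3), followed by S100A3 (5.02 ± 0.18), MDFI (4.95 ± 0.15), R3HDML (4.89 ± 0.14) and NRP2, a semaphorin and VEGF co-receptor (4.47 ± 0.20). ANGPTL2 (4.33 ± 0.16), LTBP2, which encodes a latent TGF-beta binding protein family member (4.28 ± 0.14), PCDH1 (4.18 ± 0.19), JUNB (4.05 ± 0.14) and the matrix proteoglycan gene BGN (4.04 ± 0.19) completed the 10. Their adjusted p lay between 7.09e-07 and 5.10e-06. Order and membership of the 10 hold on the variance-stabilised scale, which compresses differences near the lowest value, and can differ on another scale. ALPG (ENSG00000163286.9) lies on chromosome 2, 232406844 to 232410714 of GRCh38 and rose from 6.16 ± 0.18 to 12.58 ± 0.20; its near-identical relative ALPP can share its reads, so the gene of origin is uncertain. R3HDML had 2.19 ± 1.92 normalised reads in the controls and 1580 ± 108 with GDF11.

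The largest decreases, ranked on the same scale and dependent on it in the same way, were in GSTA1, a hepatic glutathione transferase (-3.92 ± 0.24), the pseudogene RPS27P4 (-3.47 ± 0.89), DDC, the aromatic amino acid decarboxylase (-3.45 ± 0.16), PRODH2 (-2.87 ± 0.24) and the sulfotransferase gene SULT2A1 (-2.79 ± 0.16). Next came ACSS1 (-2.75 ± 0.15), SPTLC3 (-2.63 ± 0.17), LIME1 (-2.61 ± 0.21), AKR1C1 (-2.61 ± 0.19) and the steroid dehydrogenase gene HSD17B2 (-2.54 ± 0.22). GSTA1 (ENSG00000243955.6) lies on chromosome 6, 52791371 to 52803816 of GRCh38 and fell from 11.50 ± 0.50 to 7.59 ± 0.09. GSTA1 and AKR1C1 belong to families of near-identical genes, so reads can be divided among their members. RPS27P4 shares its sequence with RPS27, and its 3 GDF11 values were 9.34, 5.52 and 5.52. Its call (adjusted p = 0.0236) ended when single libraries were left out, with differences of -3.19 without control replicate 1, -3.48 without control replicate 2, -2.83 without GDF11 replicate 2 and -2.83 without GDF11 replicate 3. It also ended with a robust variance prior (adjusted p = 0.0551) and with the RNA integrity number as a covariate (-1.53, adjusted p = 0.513).

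TGF-beta/SMAD target genes were higher: 27 of 40 rose, 1 fell and 12 were not called (31 and 2 adjusted over the list alone). The TGF-beta target list had a median log2 difference of 1.65 (camera adjusted p = 6.88e-18, adjusted p = 0.0956 with an estimated correlation). Besides LTBP2 and JUNB (ENSG00000171223.6, chromosome 19, 12791486 to 12793315), the list's largest responses included LEFTY2 at 3.16 ± 0.14, a secreted inhibitor of Nodal signalling whose reads its relative LEFTY1 can share. The feedback regulators SMAD7, an inhibitory SMAD (2.10 ± 0.29, adjusted p = 0.00124), and SKIL, a SMAD corepressor (3.06 ± 0.21, adjusted p = 3.45e-05), rose. PMEPA1, a further SMAD-regulated gene, rose by 2.61 ± 0.16 (adjusted p = 1.54e-05), with control replicates 1 and 2 at the lowest value of the table. Over this list, control replicate 3 lay at a median position of 0.15 on a scale on which 0 is the mean of control replicates 1 and 2 and 1 the GDF11 mean; the position is taken over members that differ by at least 0.5 between those means. SMAD7 stood at 1.25 with the RNA integrity number as a covariate (adjusted p = 0.0230).

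**Figure D1:**
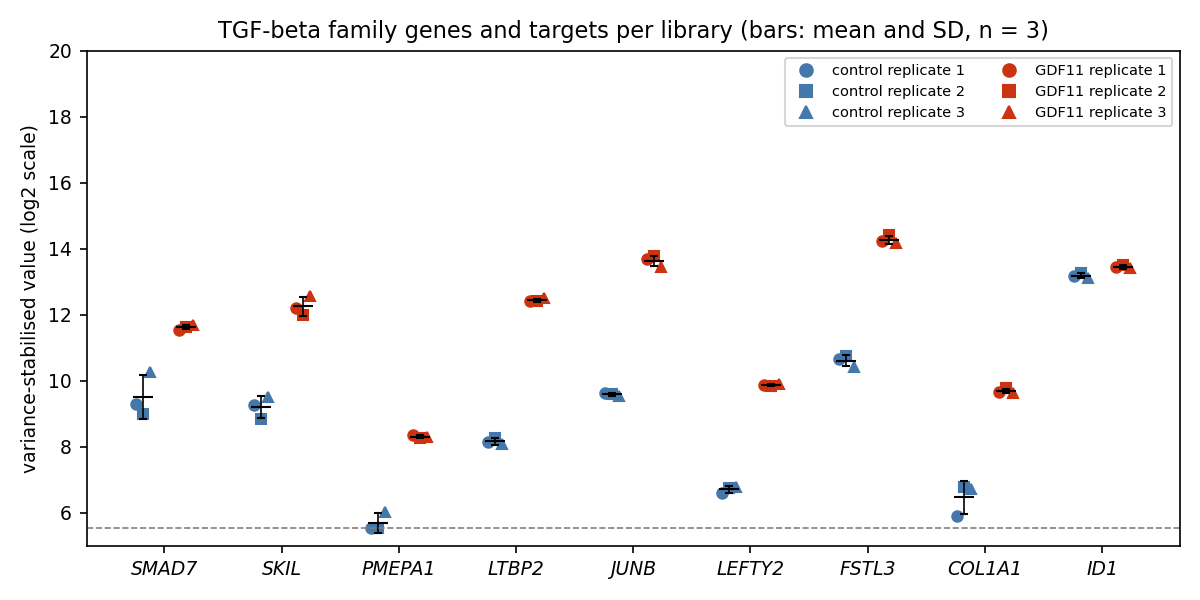
Variance-stabilised values (vertical axis, log2 scale) of 9 genes in each of the 6 libraries; blue symbols are control and red symbols GDF11 libraries, symbol shapes mark the replicate, black bars show the mean and SD of 3 libraries, and the dashed line marks the value of a gene without reads. JUNB rose from 9.59 to 13.63, while ID1 stood at 13.18 and 13.46.

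Ligand, receptor and modulator genes of the family changed as well: 15 of 31 rose, 2 fell and 14 were not called (16 and 3 adjusted over the list alone). The TGF-beta family list had a median log2 difference of 0.59 (camera adjusted p = 1.74e-05, adjusted p = 0.209 with an estimated correlation). FSTL3, which encodes an extracellular antagonist of activins and GDF11, rose by 3.66 ± 0.15, and FST, for follistatin, a related antagonist, by 2.30 ± 0.18. INHBE, an inhibin subunit gene of hepatocytes, rose by 2.45 ± 0.14 and the co-receptor gene ENG by 2.35 ± 0.17. Transcripts of GDF11 itself stood at 7.85 ± 0.13 in controls and 8.01 ± 0.056 with GDF11 (SD, n = 3 each, adjusted p = 0.429), so the gene was not called. Among BMP/SMAD1/5 target genes, 2 of 10 rose, 3 fell and 5 were not called (2 and 4 adjusted over the list alone), with a median log2 difference of 0.13 (camera adjusted p = 0.905). HEY1 (1.79 ± 0.20) and SMAD6 (1.62 ± 0.23) rose, the iron hormone gene HAMP fell by 1.49 ± 0.17, and ID1, the classical BMP target, was not called (0.27 ± 0.14, adjusted p = 0.189). ID1 was called higher with quantile normalization (0.41), with library weights (0.27), after removal of the GC and length trend (0.57) and after that removal without control replicate 3 (0.74), at adjusted p from 0.000611 to 0.0410. The ligand, receptor and modulator list had a median of 0.36 with the RNA integrity number as a covariate (adjusted p = 0.000487).

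Genes of lipid handling moved in both directions. PLIN2 (ENSG00000147872.10, chromosome 9, 19108388 to 19127492), which encodes the main coat protein of hepatocyte lipid droplets, rose from 14.10 ± 0.17 to 15.23 ± 0.10 (SD, n = 3 each; log2 difference 1.13 ± 0.16, adjusted p = 0.00153), 2.19 times the control on back-transformed reads. Among lipid droplet proteins and lipases, 3 of 21 rose, 4 fell and 14 were not called (3 and 4 adjusted over the list alone). This list was not called (a median log2 difference of 0.023, camera adjusted p = 0.841; its mean of -0.098 and the direction of the test were negative). FITM1 rose by 0.78 ± 0.13, whereas CIDEC, a droplet fusion protein gene, fell by 1.60 ± 0.19 and PLIN1 fell by 0.60 ± 0.094. In glycerolipid and triglyceride synthesis, 3 of 22 rose, 4 fell and 15 were not called (4 and 4 adjusted over the list alone), with a median log2 difference of 0.06 (camera adjusted p = 0.905). ACSL1, a long-chain acyl-CoA synthetase gene, and GPAM, for the mitochondrial glycerol-3-phosphate acyltransferase, rose by 1.35 ± 0.19 and 1.17 ± 0.18. DGAT1, which encodes an enzyme of the last step of triglyceride synthesis, fell by 2.04 ± 0.27 and MOGAT2 fell by 0.99 ± 0.15. DGAT2, the other enzyme of that step, fell by 0.81 ± 0.18 (adjusted p = 0.0134); its call ended at -0.70 without control replicate 1, -0.82 without GDF11 replicate 1 and -0.75 without GDF11 replicate 3, and at -0.42 with the RNA integrity number as a covariate (adjusted p = 0.255). With that covariate the call of PLIN1 ended too (-0.58, adjusted p = 0.0515), and DGAT1 and GPAM stood at -1.24 and 0.77. Of the lipid droplet genes, the number lower was 1 with the RNA integrity covariate. Of the triglyceride synthesis genes, the number lower was 2 without GDF11 replicate 1 or 3 and 2 with the RNA integrity covariate.

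De novo lipogenesis genes were lower: 0 of 21 rose, 5 fell and 16 were not called (2 and 6 adjusted over the list alone). The lipogenesis list had a median log2 difference of -0.40 (camera adjusted p = 0.0105, adjusted p = 0.170 with an estimated correlation). The call of this list also ended with quantile normalization (median -0.25, adjusted p = 0.0722) and with the RNA integrity number as a covariate (median -0.24, adjusted p = 0.0654). MLXIPL, the gene of the glucose-responsive lipogenic factor ChREBP, fell by 2.01 ± 0.19, ACSS2 fell by 1.25 ± 0.26 and NR1H3, for the oxysterol receptor LXR-alpha, fell by 1.10 ± 0.22. FASN, the fatty acid synthase gene, fell by 0.91 ± 0.24 (adjusted p = 0.0260), a call that ended at -0.82 without control replicate 1, -0.74 without control replicate 2, -0.97 without GDF11 replicate 1, -0.93 without GDF11 replicate 2 and -0.83 without GDF11 replicate 3. With quantile normalization FASN stood at -0.53 (adjusted p = 0.0160). Calls of FASN (-0.24, adjusted p = 0.517), ACSS2 (-0.51, adjusted p = 0.255) and NR1H3 (-0.46, adjusted p = 0.207) ended with the RNA integrity number as a covariate. Of the lipogenesis genes, the number lower was 3 without control replicate 2 or GDF11 replicate 1, 2 or 3, 9 without control replicate 3, 11 after removal of the GC and length trend and 1 with the RNA integrity covariate. The number of lipogenesis genes higher was 2 without control replicate 3 and 2 after removal of the GC and length trend. The lipogenesis median was -0.24 with library weights (adjusted p = 0.0230). SCD, the stearoyl-CoA desaturase gene, was not called (-0.35 ± 0.18, adjusted p = 0.176), nor was SREBF1 (-0.015 ± 0.17, adjusted p = 0.958). SCD was called lower after removal of the GC and length trend (-0.50, adjusted p = 0.0157) and after that removal without control replicate 3 (-0.52, adjusted p = 0.00362). INSIG1 and ME1 were listed at or next to the lowest value in the 6 libraries and were not tested; whether these cells lack them or the quantification missed them cannot be read from the table. Control replicate 3 lay at a median position of 0.63 over the lipogenesis list.

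Fatty acid oxidation and ketogenesis genes were lower: 0 of 29 rose, 10 fell and 19 were not called (0 and 10 adjusted over the list alone). The oxidation list had a median log2 difference of -0.36 (camera adjusted p = 0.000455, adjusted p = 0.137 with an estimated correlation). HADH fell by 1.52 ± 0.21, ECI2 fell by 1.37 ± 0.16, ACAA1 fell by 1.03 ± 0.17 and BDH1 fell by 1.03 ± 0.15, while CPT1A, the carnitine palmitoyltransferase gene of the entry step, was not called (-0.24 ± 0.15, adjusted p = 0.267). In fatty acid uptake and binding, 4 of 14 rose, 4 fell and 6 were not called (4 and 4 adjusted over the list alone), with a median log2 difference of -0.18 (camera adjusted p = 0.624). The fatty acid binding protein gene FABP1 fell by 1.93 ± 0.19, FABP5 fell by 0.81 ± 0.14 and SLC27A5 fell by 1.15 ± 0.23, and the fatty acid receptor gene CD36 rose by 0.97 ± 0.19. Control replicate 3 lay at 0.47 over the oxidation list and at 0.57 over the uptake list. CPT1A was called lower after removal of the GC and length trend (-0.35, adjusted p = 0.0248) and after that removal without control replicate 3 (-0.39, adjusted p = 0.00932). With the RNA integrity number as a covariate the calls of ACAA1 (-0.70, adjusted p = 0.0509), SLC27A5 (-0.59, adjusted p = 0.215) and CD36 (0.58, adjusted p = 0.172) ended, and HADH stood at -0.98. By fry the uptake list was called (adjusted p = 0.0446). Of the oxidation genes, the number lower was 5 without control replicate 1 or GDF11 replicate 2, 6 without control replicate 2 or GDF11 replicate 1 and 6 with the RNA integrity covariate. Without control replicate 3, 13 oxidation genes were called lower and 3 higher. After removal of the GC and length trend 15 were called lower and 3 higher.

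Cholesterol synthesis and uptake genes were lower: 0 of 25 rose, 12 fell and 13 were not called (0 and 13 adjusted over the list alone). The cholesterol list had a median log2 difference of -0.55 (camera adjusted p = 1.50e-05, adjusted p = 0.209 with an estimated correlation). EBP, a sterol isomerase gene, fell by 1.05 ± 0.20 and ACAT2, for an acetoacetyl-CoA-forming enzyme, fell by 0.82 ± 0.14. Among apolipoproteins and lipoprotein secretion genes, 0 of 18 rose, 7 fell and 11 were not called (0 and 9 adjusted over the list alone). The apolipoprotein list had a median log2 difference of -0.68 (camera adjusted p = 3.69e-05, adjusted p = 0.267 with an estimated correlation). APOM fell by 1.66 ± 0.29, MTTP, which loads lipid onto apolipoprotein B, fell by 1.37 ± 0.18, LCAT fell by 1.25 ± 0.23 and APOA5 fell by 1.19 ± 0.22. APOB (ENSG00000084674.15, chromosome 2, 21001429 to 21044073) fell from 17.55 ± 0.24 to 16.71 ± 0.23 (adjusted p = 0.0205), and its call ended at -0.88 without control replicate 1, -0.76 without GDF11 replicate 1 and -0.78 without GDF11 replicate 2 and, with quantile normalization, at -0.41. Control replicate 3 lay at 0.70 over the cholesterol list and at 0.71 over the apolipoprotein list, nearer to the GDF11 mean than to the other controls. The apolipoprotein median was -0.21 with the RNA integrity number as a covariate (adjusted p = 0.0213). In that setting APOB stood at -1.29, and the calls of APOM (-0.79), APOA5 (-0.63), LCAT (-0.58) and EBP (-0.53) ended, at adjusted p from 0.102 to 0.136. Of the cholesterol genes, the number lower was 6 without GDF11 replicate 1, 7 without control replicate 1 or 2 or GDF11 replicate 2 or 3 and 3 with the RNA integrity covariate. Of the apolipoprotein genes, the number lower was 14 without control replicate 3 and 2 with the RNA integrity covariate. Without control replicate 3, 18 cholesterol genes were called lower, and 1 cholesterol and 1 apolipoprotein gene higher.

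**Figure D2:**
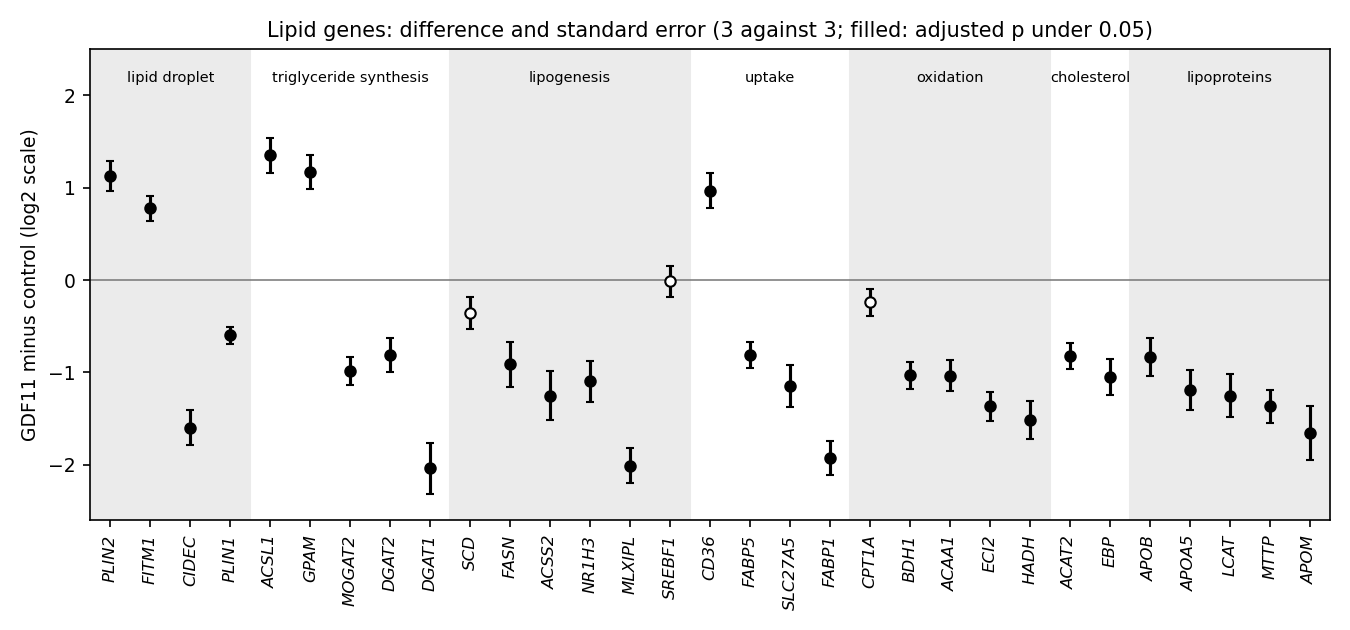
Difference between the GDF11 and control means (vertical axis, log2 scale) with its standard error for 31 lipid genes grouped by function, 3 libraries against 3; filled points have an adjusted p under 0.05. PLIN2, FITM1, ACSL1, GPAM and CD36 lie above 0, and DGAT1, MLXIPL and FABP1 lie lowest, at -2.04, -2.01 and -1.93.

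Hepatocyte secreted protein genes were lower: 1 of 33 rose, 16 fell and 16 were not called (1 and 18 adjusted over the list alone). The secreted protein list had a median log2 difference of -0.48 (camera adjusted p = 4.37e-07, adjusted p = 0.274 with an estimated correlation). The fibrinogen chain genes FGA, FGG and FGB fell by 2.20 ± 0.18, 2.03 ± 0.16 and 1.42 ± 0.16, and KNG1, for kininogen, fell by 1.46 ± 0.15. ALB, the albumin gene, fell from 17.92 ± 0.048 to 17.17 ± 0.087 (adjusted p = 0.0147); its call ended at -0.80 without GDF11 replicate 1, -0.71 without GDF11 replicate 2 and -0.75 without GDF11 replicate 3 and, with quantile normalization, at -0.29. With the RNA integrity number as a covariate the adjusted p of ALB was 0.0509 (-0.74), and the complement median was -0.21 (adjusted p = 0.0138). Acute phase genes, which share the fibrinogens and HAMP with other lists, were lower (1 of 17 rose, 9 fell, 7 not called, 2 and 9 adjusted over the list alone), with a median log2 difference of -0.55 (camera adjusted p = 0.00115, adjusted p = 0.267 with an estimated correlation). Complement genes were lower too (0 of 17 rose, 5 fell, 12 not called, 0 and 5 adjusted over the list alone), with a median log2 difference of -0.43 (camera adjusted p = 0.000850, adjusted p = 0.373 with an estimated correlation), with MASP1 at -1.07 ± 0.16 and C5 at -1.10 ± 0.19. The position of control replicate 3 was 0.31, 0.21 and 0.31 over the secreted, acute phase and complement lists. Of the secreted protein genes, the number lower was 10 without GDF11 replicate 3 and 10 with the RNA integrity covariate. The secreted protein median was -0.75 on a log2 scale of reads plus 1 (adjusted p = 3.37e-07). The acute phase median was -0.30 with no filter (adjusted p = 0.000118) and -0.31 after removal of the GC and length trend without control replicate 3 (adjusted p = 0.0325). Of the complement genes, the number lower was 8 without control replicate 3, 9 after removal of the GC and length trend and 3 with the RNA integrity covariate. The complement median was -0.22 with no filter (adjusted p = 0.000228) and -0.27 with quantile normalization (adjusted p = 0.00717).

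Of hepatocyte transcription factor genes, 2 of 20 rose, 10 fell and 8 were not called (2 and 12 adjusted over the list alone). The transcription factor list had a median log2 difference of -0.55 (camera adjusted p = 0.00812, adjusted p = 0.209 with an estimated correlation). NR1H4, the bile acid receptor FXR, fell by 1.57 ± 0.17, whereas NR1I2, the xenobiotic receptor PXR, rose by 1.48 ± 0.18. For bile acid synthesis and transport, 1 of 16 rose, 7 fell and 8 were not called (2 and 10 adjusted over the list alone). The bile acid list had a median log2 difference of -0.58 (camera adjusted p = 0.00265, adjusted p = 0.207 with an estimated correlation). SLC51B, an organic solute transporter subunit gene, fell by 1.72 ± 0.21 and CYP7A1, the rate-limiting enzyme of bile acid synthesis, fell by 0.87 ± 0.13, with GDF11 replicates 1 and 2 at the lowest value, and by 3.96 on a log2 scale of reads plus 1. Of drug metabolism genes, 2 of 21 rose, 9 fell and 10 were not called (2 and 10 adjusted over the list alone). The drug metabolism list had a median log2 difference of -0.46 (camera adjusted p = 0.00484, adjusted p = 0.131 with an estimated correlation). UGT2B10 fell by 1.85 ± 0.17 and GSTA2, near-identical to GSTA1, fell by 2.32 ± 0.14. In amino acid catabolism and the urea cycle, 1 of 21 rose, 10 fell and 10 were not called (1 and 10 adjusted over the list alone). The amino acid list had a median log2 difference of -0.42 (camera adjusted p = 0.000514, adjusted p = 0.131 with an estimated correlation), with MAT1A at -2.30 ± 0.16 and AGXT at -2.08 ± 0.23. Over these 4 lists the position of control replicate 3 was 0.61, 0.42, 0.14 and 0.10. With the RNA integrity number as a covariate the transcription factor list lost its call (median -0.22, adjusted p = 0.0522), and the bile acid median was -0.38 (adjusted p = 0.0299). The drug metabolism median was -0.28 without control replicate 3 (adjusted p = 0.0186), and the amino acid median was -0.26 without control replicate 2 (adjusted p = 0.000797). Of the transcription factor genes, the number lower was 3 without GDF11 replicate 3, 4 without GDF11 replicate 1, 5 without control replicate 1 or 2, 6 without GDF11 replicate 2 and 3 with the RNA integrity covariate. Of the bile acid genes, the number lower was 4 without control replicate 1 and 3 with the RNA integrity covariate. The drug metabolism median was -0.12 with no filter (adjusted p = 0.000175) and -0.27 after removal of the GC and length trend without control replicate 3 (adjusted p = 0.0145). The amino acid median was -0.64 on a log2 scale of reads plus 1 (adjusted p = 0.000508).

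Fetal liver and hepatocellular carcinoma markers were not called as a list (a median log2 difference of -0.16, camera adjusted p = 0.824, with a mean of opposite sign, 0.072); 2 of 15 rose, 4 fell and 9 were not called (4 and 4 adjusted over the list alone). GOLM1 rose by 2.06 ± 0.18 and KRT19, a bile duct keratin gene, by 1.48 ± 0.21. PEG10 and MDK were among the 4 that fell. Their calls ended at -1.01 and -0.81 without control replicate 1 (adjusted p = 0.0620 and 0.0960). For gluconeogenesis and glycogen, 1 of 14 rose, 4 fell and 9 were not called (2 and 6 adjusted over the list alone), with a median log2 difference of -0.23 (camera adjusted p = 0.236), with G6PC1, the glucose-6-phosphatase gene, at -1.96 ± 0.30. Among glycolysis genes, 5 of 25 rose, 8 fell and 12 were not called (6 and 13 adjusted over the list alone), with a median log2 difference of -0.52 (camera adjusted p = 0.149); the glucose transporter genes SLC2A3 and SLC2A1 rose by 1.34 ± 0.17 and 0.97 ± 0.19. Without control replicate 3 the glycolysis list was called lower (median -0.45, adjusted p = 0.0201); that library lay at 0.55. Without a filter it was called lower too (median -0.40, adjusted p = 0.0345), as it was after removal of the GC and length trend without control replicate 3 (median -0.45, adjusted p = 0.0234). By fry the gluconeogenesis list was called (adjusted p = 0.0122), and with the RNA integrity number as a covariate the call of G6PC1 ended (-1.81, adjusted p = 0.0534). Of the fetal liver genes, the number lower was 0 without control replicate 1 or GDF11 replicate 1 or 2, 1 without GDF11 replicate 3 and 2 without control replicate 2. Of the gluconeogenesis genes, the number lower was 2 without GDF11 replicate 1, 2 or 3 and 1 with the RNA integrity covariate. Of the glycolysis genes, the number lower was 2 without control replicate 1 or GDF11 replicate 3, 3 without control replicate 2 or GDF11 replicate 1 or 2, 15 without control replicate 3 and 2 with the RNA integrity covariate.

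Mesenchymal and EMT genes were higher: 12 of 22 rose, 1 fell and 9 were not called (14 and 1 adjusted over the list alone). The mesenchymal list had a median log2 difference of 0.68 (camera adjusted p = 7.06e-06, adjusted p = 0.0956 with an estimated correlation). CDH2, the N-cadherin gene, rose by 1.80 ± 0.20, TAGLN, an actin-binding protein gene of smooth muscle, by 1.68 ± 0.21 and S100A11 by 2.60 ± 0.20, while VIM was listed at or next to the lowest value and, like INSIG1, not tested. Epithelial junction and keratin genes were also higher as a list: 7 of 22 rose, 2 fell and 13 were not called (9 and 2 adjusted over the list alone). The epithelial list had a median log2 difference of 0.42 (camera adjusted p = 0.0285, adjusted p = 0.196 with an estimated correlation). CDH1, the E-cadherin gene, rose from 10.16 ± 0.77 to 13.97 ± 0.014, and the keratin genes KRT8 and KRT19 rose by 1.28 ± 0.24 and 1.48 ± 0.21; TJP3, a tight junction protein gene, fell by 1.45 ± 0.25. With the RNA integrity number as a covariate the epithelial list lost its call (median 0.18, adjusted p = 0.0977), and so did TJP3 (-0.75, adjusted p = 0.102). Control replicate 3 lay at 0.30 over the mesenchymal and 0.50 over the epithelial list. Of the mesenchymal genes, the number higher was 7 without GDF11 replicate 1. Of the epithelial genes, the number higher was 3 without GDF11 replicate 1 and 4 without control replicate 1 or GDF11 replicate 3. The epithelial median was 0.28 with no filter (adjusted p = 0.00921).

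In extracellular matrix and matrix remodelling, 16 of 33 rose, 2 fell and 15 were not called (17 and 2 adjusted over the list alone). The matrix list had a median log2 difference of 0.64 (camera adjusted p = 1.94e-05, adjusted p = 0.226 with an estimated correlation). The collagen cross-linking enzyme genes LOXL4 and LOXL2 rose by 3.32 ± 0.14 and 2.40 ± 0.17, COL1A1, a fibrillar collagen gene, by 3.22 ± 0.23 and MMP9 by 1.78 ± 0.12. For the actin cytoskeleton and focal adhesion, 15 of 26 rose, 0 fell and 11 were not called (17 and 0 adjusted over the list alone). The actin list had a median log2 difference of 0.86 (camera adjusted p = 1.84e-08, adjusted p = 0.0956 with an estimated correlation). Among its called members were the integrin genes ITGA3 (2.70 ± 0.17), ITGAV (2.58 ± 0.33) and ITGA2 (2.12 ± 0.27). Of YAP/TAZ targets, 7 of 17 rose, 0 fell and 10 were not called (10 and 0 adjusted over the list alone). The YAP/TAZ list had a median log2 difference of 0.53 (camera adjusted p = 2.49e-05, adjusted p = 0.300 with an estimated correlation); CCN1 and ANKRD1 rose by 1.85 ± 0.15 and 1.99 ± 0.20, and the list lost its call with the RNA integrity number as a covariate (median 0.11, adjusted p = 0.0551). Of immediate early genes, 10 of 18 rose, 1 fell and 7 were not called (11 and 2 adjusted over the list alone). The immediate early list had a median log2 difference of 0.69 (camera adjusted p = 3.20e-05, adjusted p = 0.131 with an estimated correlation), with ZFP36 at 1.99 ± 0.16 and JUN at 1.60 ± 0.19. Wnt/beta-catenin targets were not called as a list, with a median log2 difference of 0.68 (camera adjusted p = 0.236): 8 of 15 rose, 3 fell and 4 were not called (8 and 4 adjusted over the list alone), among them DKK1, a secreted Wnt inhibitor (1.68 ± 0.19), LGR5 (1.27 ± 0.18) and the glutamine synthetase gene GLUL (-1.30 ± 0.17). Over these 5 lists the position of control replicate 3 was 0.089, 0.31, 0.38, -0.017 and 0.35. By fry the Wnt list was called (adjusted p = 0.0432). The matrix median was 0.34 with the RNA integrity number as a covariate (adjusted p = 4.52e-06), and ITGAV and ITGA2 stood at 1.58 and 1.28. The matrix median was 0.28 with no filter (adjusted p = 6.08e-07). Of the YAP/TAZ genes, the number higher was 15 without control replicate 3 and 4 with the RNA integrity covariate. Of the Wnt target genes, the number higher was 5 without control replicate 1 or 2 or GDF11 replicate 1, 2 or 3 and 5 with the RNA integrity covariate.

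G1/S and DNA replication genes were lower: 0 of 30 rose, 25 fell and 5 were not called (0 and 26 adjusted over the list alone). The G1/S list had a median log2 difference of -0.88 (camera adjusted p = 4.17e-13, adjusted p = 0.0552 with an estimated correlation). E2F2 fell by 1.46 ± 0.16, CDC25A, an activating phosphatase of G1/S kinases, fell by 1.43 ± 0.16, and the replication factor gene RFC3 fell by 1.15 ± 0.14. Of G2/M and mitosis genes, 0 of 34 rose, 20 fell and 14 were not called (0 and 27 adjusted over the list alone). The G2/M list had a median log2 difference of -0.63 (camera adjusted p = 3.46e-10, adjusted p = 0.116 with an estimated correlation), with CCNA2 at -1.02 ± 0.14 and AURKA at -0.85 ± 0.13. CDKN1A, the gene of the kinase inhibitor p21, rose by 1.01 ± 0.16. Control replicate 3 lay with the other controls over the G1/S list, at -0.0027, and at 0.16 over the G2/M list. Among MYC targets and ribosome biogenesis genes, 0 of 22 rose, 10 fell and 12 were not called (0 and 15 adjusted over the list alone). The MYC target list had a median log2 difference of -0.54 (camera adjusted p = 2.49e-06, adjusted p = 0.0956 with an estimated correlation); the nucleolar protein gene NOP56 fell by 0.88 ± 0.15, and control replicate 3 lay at 0.55. Of the G2/M genes, the number lower was 10 without GDF11 replicate 2, 12 without control replicate 1, 13 without GDF11 replicate 1 and 13 with the RNA integrity covariate. Of the MYC target genes, the number lower was 3 without GDF11 replicate 1 or 3, 5 without control replicate 1 or 2, 16 without control replicate 3, 17 after removal of the GC and length trend and 3 with the RNA integrity covariate.

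Ribosomal protein and respiratory chain genes were lower as lists by camera (adjusted p = 0.594 and 0.542 with an estimated correlation), and control replicate 3 lay with the GDF11 libraries over both, at 0.91 and 0.85. Of 50 cytosolic ribosomal protein genes, limma called 0 higher and 0 lower, over all genes and adjusted over the list alone, while 37 were lower at an unadjusted p under 0.05. Without control replicate 3, 45 of them were called lower, and after removal of the GC and length trend 13. The ribosomal protein list had a median log2 difference of -0.67 (camera adjusted p = 2.02e-07, adjusted p = 0.594 with an estimated correlation). RPS2 stood at -0.73 ± 0.24 and RPS3 at -0.90 ± 0.30, neither called, and both were called without control replicate 3 (-0.95 and -1.26), with library weights (-0.79 and -1.13) and after removal of the GC and length trend without that library (-0.52 and -1.15). RPS2 was also called with quantile normalization (-0.31, adjusted p = 0.0389), with no filter (adjusted p = 0.0465), with no mean trend (adjusted p = 0.0372) and after the plain trend removal (-0.48, adjusted p = 0.0266). Of nuclear-encoded respiratory chain genes, 0 of 35 rose, 8 fell and 27 were not called (0 and 14 adjusted over the list alone). The respiratory chain list had a median log2 difference of -0.58 (camera adjusted p = 2.15e-06, adjusted p = 0.542 with an estimated correlation); ATP5MC1 fell by 1.46 ± 0.25, a call that ended at -0.85 with the RNA integrity number as a covariate (adjusted p = 0.105). Of the respiratory chain genes, the number lower was 1 without control replicate 1 or 2 or GDF11 replicate 1 or 3, 3 without GDF11 replicate 2, 32 without control replicate 3, 13 after removal of the GC and length trend and 0 with the RNA integrity covariate. Both lists lost their call in fry, at adjusted p of 0.138 and 0.104, and with the RNA integrity number as a covariate, at medians of 0.012 and -0.031. Mitochondrially encoded genes were not called as a list: limma called 0 of 13 higher and 0 lower, over all genes and adjusted over the list alone (0 and 1 at an unadjusted p under 0.05), with a median log2 difference of -0.11 (camera adjusted p = 0.616). Without control replicate 3, which lay at 1.43, that list was lower (median -0.41, adjusted p = 0.0254; 4 genes called), and with the RNA integrity covariate it was higher (median 0.61, adjusted p = 0.000487). The ribosomal protein median was -0.27 with quantile normalization (adjusted p = 0.000527).

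**Figure D3:**
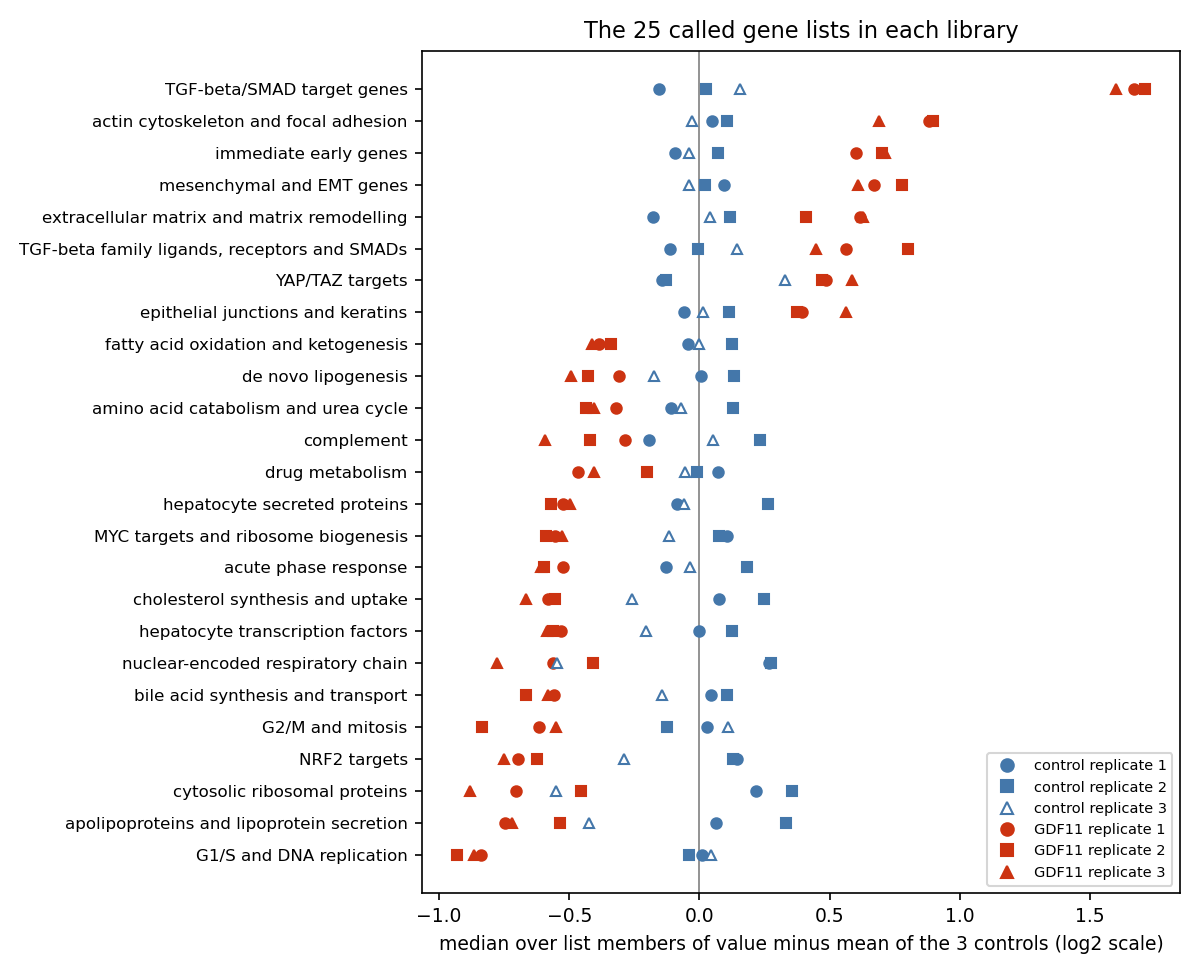
For the 25 called gene lists, the median over the list's tested members of the value in a library minus the mean of the 3 controls (horizontal axis, log2 scale); blue symbols are control libraries, with control replicate 3 open, and red symbols GDF11 libraries. Control replicate 3 lies among the GDF11 libraries for cytosolic ribosomal proteins and the respiratory chain, and with the other controls for G1/S and DNA replication.

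NRF2 targets were lower: 0 of 18 rose, 9 fell and 9 were not called (0 and 10 adjusted over the list alone). The NRF2 list had a median log2 difference of -0.66 (camera adjusted p = 3.20e-05, adjusted p = 0.131 with an estimated correlation). The aldo-keto reductase genes AKR1B10 and AKR1C2 fell by 2.08 ± 0.19 and 1.81 ± 0.17, and control replicate 3 lay at 0.55. The other stress and signalling lists were not called by camera, while fry called ATF4 and unfolded protein response (adjusted p = 0.0283) and p53 targets (adjusted p = 0.0252). In ATF4 and unfolded protein response, 3 of 25 rose, 4 fell and 18 were not called (3 and 7 adjusted over the list alone), with a median log2 difference of -0.087 (camera adjusted p = 0.212), with the serine synthesis gene PHGDH at -1.70 ± 0.28. Of p53 targets, 3 of 17 rose, 2 fell and 12 were not called (3 and 2 adjusted over the list alone), with a median log2 difference of -0.059 (camera adjusted p = 0.824), a mean of 0.11 and a test in the higher direction. Of hypoxia response genes, 4 of 20 rose, 7 fell and 9 were not called (4 and 7 adjusted over the list alone), with a median log2 difference of 0.16 (camera adjusted p = 0.900), a mean of -0.094 and a test in the lower direction; DDIT4 rose by 1.48 ± 0.14 and EPO, the erythropoietin gene, fell by 1.99 ± 0.20. Of metallothioneins, 1 of 6 rose, 2 fell and 3 were not called (1 and 2 adjusted over the list alone), with a median log2 difference of -0.025 (camera adjusted p = 0.699): MT2A rose by 1.70 ± 0.24 and MT1G fell by 1.91 ± 0.29, genes alike enough to share reads. For iron metabolism, 3 of 12 rose, 4 fell and 5 were not called (4 and 4 adjusted over the list alone), with a median log2 difference of 0.051 (camera adjusted p = 0.910), with BMP6 at 1.49 ± 0.12 and TMPRSS6, a suppressor of hepcidin, at 1.61 ± 0.16. With the RNA integrity number as a covariate the calls of PHGDH (-0.90, adjusted p = 0.0624) and MT1G (-1.05, adjusted p = 0.0511) ended. For TFR2, an iron metabolism list member that fell, the call ended in that setting too (-0.80, adjusted p = 0.0708). Of the NRF2 target genes, the number lower was 5 with the RNA integrity covariate. The NRF2 target median was -0.36 with quantile normalization (adjusted p = 0.000334). Of the ATF4 list genes, the number lower was 2 without GDF11 replicate 1, 9 without control replicate 3 and 2 with the RNA integrity covariate. Of the hypoxia response genes, the number lower was 2 without GDF11 replicate 3, 3 without GDF11 replicate 2, 4 without GDF11 replicate 1 and 2 with the RNA integrity covariate. The number of hypoxia response genes higher was 7 without control replicate 3. Of the iron metabolism genes, the number lower was 2 without control replicate 1 or 2 or GDF11 replicate 1, 2 or 3 and 1 with the RNA integrity covariate.

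Among interferon-stimulated genes, 4 of 23 rose, 2 fell and 17 were not called (4 and 3 adjusted over the list alone), with a median log2 difference of -0.12 (camera adjusted p = 0.824) and a mean of 0.015; OAS1 rose by 0.92 ± 0.14 (0.58 after removal of the GC and length trend without control replicate 3, adjusted p = 0.00776) and IRF9 by 1.22 ± 0.18. Of NF-kB and inflammatory genes, 3 of 12 rose, 2 fell and 7 were not called (3 and 2 adjusted over the list alone), with a median log2 difference of 0.071 (camera adjusted p = 0.497), with TNFAIP2 at 2.95 ± 0.25, and fry called the list (adjusted p = 0.00598). Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, were not called as a list, with a median log2 difference of 0.078 (camera adjusted p = 0.491): 3 of 16 rose, 0 fell and 13 were not called (4 and 1 adjusted over the list alone), with H2AC6 at 1.08 ± 0.14. Whether the H2AC6 transcripts had a tail cannot be read from these values. The histone list was called higher with the RNA integrity number as a covariate (median 0.10, adjusted p = 0.0492). Markers of other cells were not called as lists by camera, while fry called endothelial markers (adjusted p = 0.00761). Of fibroblast markers, 1 of 4 rose, 0 fell and 3 were not called (1 and 0 adjusted over the list alone), with a median log2 difference of -0.069 (camera adjusted p = 0.979) and a mean of 0.037; COL1A2, COL3A1, DCN, LUM and POSTN were below the filter. Of leukocyte markers, 2 of 7 rose, 1 fell and 4 were not called (2 and 2 adjusted over the list alone), with a median log2 difference of -0.044 (camera adjusted p = 0.841), and PTPRC was listed at the lowest value. Of endothelial markers, 2 of 4 rose, 1 fell and 1 were not called (2 and 1 adjusted over the list alone), with a median log2 difference of 0.46 (camera adjusted p = 0.491); the adhesion molecule gene ESAM rose by 2.75 ± 0.16 and VWF fell by 0.87 ± 0.15, a call that ended at -0.59 with the RNA integrity number as a covariate (adjusted p = 0.127).

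The 45 lists gave 25 calls, 8 higher and 17 lower, and these 25 lists were also called, in the same direction, when any 1 library was left out. The calls are not independent, as lists share genes. TAGLN is in the TGF-beta target and mesenchymal lists, for example, and CCN1 in the TGF-beta and YAP/TAZ target lists. With an estimated correlation none of the 45 was called, the lowest adjusted p being 0.0552; fry called 30. Counts of fewer than 4 called members moved by at most 3 when 1 library was left out, in lists with any call. Library values also followed the make-up of the transcripts. Across the 9429 genes with a mean of at least 9, the difference between GDF11 and control fell with GC content (Spearman rho -0.23) and rose with transcript length (rho 0.31); genes are not independent replicates. The median difference was 0.12 in the lowest and -0.30 in the highest GC decile, and -0.38 for the shortest and 0.22 for the longest decile. Control replicate 3 against the other controls followed the same properties, with rho of -0.52 and 0.52.

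**Figure D4:**
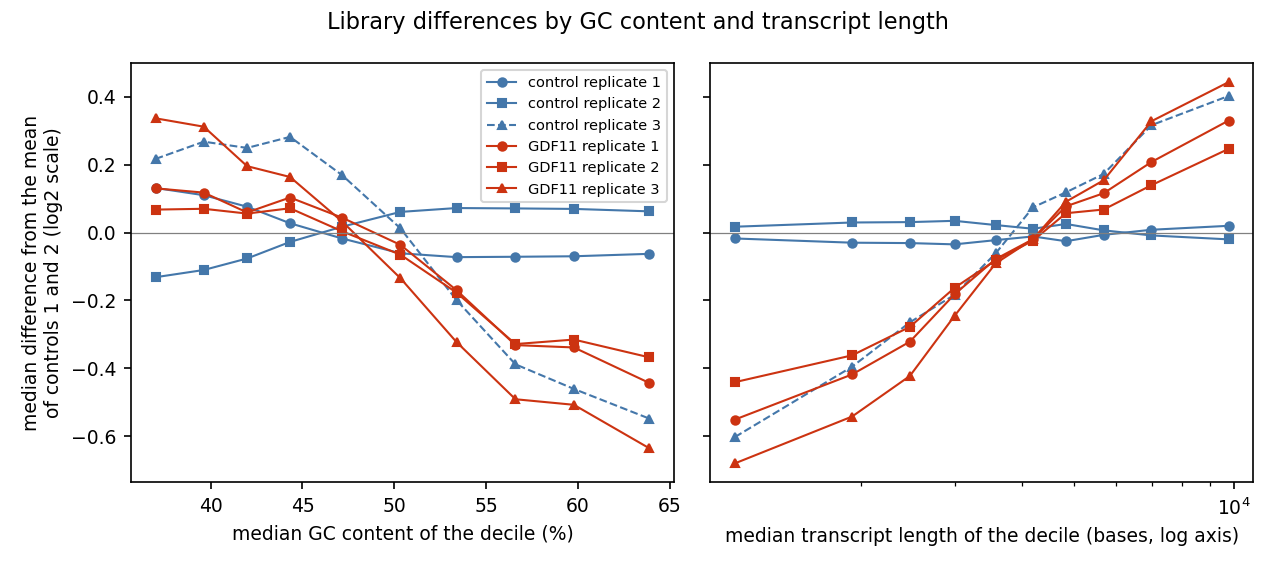
Median difference of each library from the mean of control replicates 1 and 2 (vertical axis, log2 scale) in deciles of the genes by GC content (left, percent) and by transcript length (right, bases, log axis); blue lines are control libraries, with control replicate 3 dashed, and red lines GDF11 libraries. In the most GC-rich decile control replicate 3 stands at -0.55 and the GDF11 libraries at -0.37 to -0.64.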

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

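The counts of called genes moved with the RNA integrity covariate, the library weights and the left-out libraries; causes were not tested unless named. Left-out libraries gave 1397 to 3647 higher genes and 955 to 3993 lower genes, the highest of each without control replicate 3, against 2185 and 2017; fewer libraries remain in each. Library weights called 4473 higher and 4554 lower, the RNA integrity covariate 1149 and 721, and limma's treat against 0.25, a stricter question by construction, 1176 and 846. The GC and length trend removal without control replicate 3, chosen after seeing the data like the plain removal and the scale of reads plus 1, called 3849 and 4054. Both filters, quantile normalization, median centring, the variance priors, the plain removal and the scale of reads plus 1 stayed within 1.5 times (1893 to 2869 higher, 1729 to 2873 lower).

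Fitted with the replicate number as a block, the counts were 3147 higher and 3306 lower. Same-numbered libraries deviated together with correlations of -0.088, 0.38 and 0.48, control replicate 1 deviated most like GDF11 replicate 2, and the numbers do not pair the libraries by the labels; the block ended no list call, and it called RPS2 (-0.73, adjusted p = 0.00907) and RPS3 (-0.90, adjusted p = 0.00490).

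The variance share between groups was 74.8% over 5000 genes and 66.5% over all tested genes, and 83.2% to 88.3% with 1 library left out. With an estimated correlation the 5 called primary lists lost their call at unchanged medians (1.65, -0.40, -0.36, -0.55 and -0.68), their adjusted p going from between 6.88e-18 and 0.0105 to between 0.0956 and 0.267. With an estimated correlation after the GC and length trend removal, a test added after seeing the data, none was called either, at 1.66, -0.50, -0.42, -0.49 and -0.53 (adjusted p from 0.141 to 0.243). De novo lipogenesis lost its call with quantile normalization (-0.25) and the RNA integrity covariate (-0.24), its adjusted p ranging from 0.000837 to 0.170 over the alternatives. Fatty acid uptake and binding was called by fry (-0.18, adjusted p = 0.0446). Mitochondrially encoded genes turned to 0.61 with the RNA integrity covariate, which follows the groups in part. Of 196 named genes, the covariate ended 42 calls and single left-out libraries 12 to 18, except control replicate 3, which ended 0; none turned a called gene's direction.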

Other observations

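The family, PPAR-alpha and control replicate 3 tests and the removal of the GC and length trend were chosen after the results were seen. Genes were also grouped by the letters with which their symbols start, giving 358 families of at least 6 tested members, of which camera called 9 higher and 17 lower. A family holds whatever shares the letters, antisense transcripts included: of the families named here, 2 of 14 for KRT, 1 of 6 for CLEC, 2 of 6 for TNS and 2 of 52 for MRPL have an antisense suffix. None of these 26 families was called with an estimated correlation (lowest adjusted p = 0.759 with an estimated correlation). The KRT family was higher (9 of 14 higher and 0 lower, median 1.06, adjusted p = 8.04e-05, adjusted p = 0.759 with an estimated correlation), as were CLEC (4 of 6 higher and 0 lower, median 1.44, adjusted p = 0.00182, adjusted p = 0.759 with an estimated correlation), TNS (4 of 6 higher and 0 lower, median 0.85, adjusted p = 0.0449, adjusted p = 0.759 with an estimated correlation), whose 4 called members are the tensin genes TNS1 to TNS4, and HOXA (3 of 10 higher and 0 lower, median 0.32, adjusted p = 0.0473, adjusted p = 0.759 with an estimated correlation). The called CLEC members were CLEC16A, CLEC18A, CLEC18B and CLEC18C, while CLEC2D was not called. Whether reads were divided among the CLEC18 genes was not tested. The mitochondrial ribosomal protein families were lower (0 of 52 higher and 18 lower, median -0.55, adjusted p = 2.28e-06, adjusted p = 0.759 with an estimated correlation for MRPL and 0 of 30 higher and 10 lower, median -0.40, adjusted p = 0.000803, adjusted p = 0.759 with an estimated correlation for MRPS), with control replicate 3 at 0.78 and 0.77. POLR, mostly RNA polymerase subunit genes (0 of 32 higher and 8 lower, median -0.45, adjusted p = 0.00492, adjusted p = 0.759 with an estimated correlation), and CDCA (0 of 6 higher and 6 lower, median -0.99, adjusted p = 0.000803, adjusted p = 0.759 with an estimated correlation) were lower too, with control replicate 3 at 0.81 and -0.031. After the GC and length trend was removed, with the preset correlation alone, KRT (median 1.22, adjusted p = 5.75e-05) and MRPL (median -0.42, adjusted p = 5.75e-05) were still called, while HOXA (median 0.34, adjusted p = 0.0513) and TNS (median 0.79, adjusted p = 0.0593) were not, at medians close to those before. The families SNHG, TIMM, COA, TOMM, SLC4A, DNAH, NPIPB, COQ, PSMB and SLC25A also lost their camera call (adjusted p from 0.0593 to 0.123). The rest of the 26 families kept theirs.

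Short and GC-rich genes were lower with GDF11, and control replicate 3 shared this with the GDF11 libraries while keeping control levels of replication genes. A trend of the libraries on GC and length as the whole cause was examined by its removal. Camera at its preset correlation still called the lists lower. Medians were -0.54 for cytosolic ribosomal proteins, -0.47 for the respiratory chain and -0.89 for G1/S. They were -0.53 for apolipoproteins, -0.49 for cholesterol synthesis and -0.48 for secreted proteins. With control replicate 3 also left out, the 6 medians were -0.79, -0.62, -0.92, -0.65, -0.67 and -0.46. For ribosomal proteins, the respiratory chain, apolipoproteins and cholesterol synthesis the removal cannot decide, as that untreated library still lay towards the GDF11 libraries. For G1/S and secreted proteins, whose medians hardly moved, it argues against that trend as the whole cause. In the order of the medians, the 6 lists had adjusted p = 0.594, 0.542, 0.0552, 0.267, 0.209 and 0.274 with an estimated correlation before the removal and 0.604, 0.576, 0.141, 0.185, 0.243 and 0.351 after it, so none was called that way. A wrong label, or treated RNA mixed into control replicate 3 as the source of its place among the GDF11 libraries, is argued against by its share of reads over the 28 called TGF-beta/SMAD targets, 0.031 (quartiles 0.0056 and 0.11), where 1 is the GDF11 mean. A small share of mixed RNA is not excluded. Mixing predicts 1 share for all changed genes, and over the called lower respiratory chain and apolipoprotein genes it was 0.66 (quartiles 0.61 and 0.80). Over target list members taken without regard to a call, the median position was 0.15. The 28 targets themselves were called with control replicate 3 counted as a control, which favours a low share. A partial exposure of that culture stays open (position 0.12 over the same targets, between the bounds set for either reading), and so does RNA integrity: in 5 of 6 within-group pairs the library with the lower number had the lower GC-rich against GC-poor difference, and with the number as a covariate the ribosomal and respiratory chain medians went to 0.012 and -0.031, but the numbers follow the groups in part (9.6 to 9.9 against 9.4 to 9.6); an effect of GDF11 on these genes was not tested apart from it.

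PLIN2 rose while lipogenesis, cholesterol and apolipoprotein genes were lower by camera (adjusted p = 0.170, 0.209 and 0.267 with an estimated correlation). The lipogenesis call also ended with quantile normalization (median -0.25, adjusted p = 0.0722) and with the RNA integrity covariate (median -0.24, adjusted p = 0.0654). PLIN2 is a known PPAR-alpha target, and a candidate explanation is a joint rise of such targets. The tables argue against it: the other PPAR-alpha target genes had a median of -0.24 over 15 tested members, with 1 higher and 4 lower (camera p = 0.293, p = 0.579 with an estimated correlation). A direct effect of GDF11 on PLIN2, or an effect of stored lipid, stays open, as neither can be told from RNA of 1 time point.

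The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, called 4202 genes and the highest other split 3. It called 25 lists, also more than any other split, where the highest was 16, so other splits call lists too. Each other split mixes control and GDF11 libraries within its groups. The treatment difference then widens the spread within groups, which keeps gene calls few, and part of it stays between groups. The calls of the other splits are therefore not rates without treatment, and no conclusion on chance is drawn from them.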
